A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

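The data are 13 two-colour arrays of budding yeast labelled yox1 yhp1, 1 for each time point from 0 to 120 min after release from alpha factor, taken from the table of processed values deposited for the series. Per the labels, Cy5 marks the time-point sample and Cy3 an unsynchronised wild-type culture grown overnight to an optical density given there, with no dye swap and no replicates. The table holds 6217 rows, of which 6205 carry a yeast gene identifier and 12 are control spots that were left out (2 of these have no values). No scanner files were used here, so spot brightness and signal over background are unknown. The deposited values are log ratios that were read as log10, sample over reference. The base is inferred: 18 values sit at exactly 2 or -2, a limit of 100-fold in base 10 and of 4-fold in base 2, the largest other value is 1.61, and the scatter around the fitted curves would be 10.5% in base 10 and 3.06% in base 2. The sign follows the dyes in the labels. How the authors corrected background, normalised, filtered and limited the values is not given in the sources used here. The deposited medians by array, from 0 to 120 min, were 0.0039, 0.0026, 0.0027, 0.0030, 0.0063, 0.0078, 1.66e-05, -3.815e-05, 0.0043, 0.0032, 0.0069, 0.0066 and 0.0058, so the arrays had been centred near 0 before deposit by a method that stays unknown. Dye bias and any normalisation that assumes most genes unchanged would enter every difference from the reference.

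Gene symbols came from a reference table of assembly R64, matched on locus tag for 5704 of 6205 identifiers. The other 501 keep their identifier. That table was used for names and for gene order only. Each gene has 1 row.

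The rule for several probes of a gene was therefore not needed. Values at 2 or -2 were set to missing, a choice made after seeing the data, and each array was centred on its median. A gene needed values on 10 of 13 arrays, which left out 54 genes and kept 6151. Fits used limma 3.58.1 in R 4.3.3 with lmFit and eBayes on an intercept, linear time, and a cosine and sine of the cycle. The period was that between 50 and 80 min, in steps of 1 min, with the smallest residual on the mean of the G1/S list, and was 63 min (60 min if the course is divided into the 2 cycles of the labels). A moderated F test of cosine and sine gave periodic genes, the intercept against 0 with at least 1.5-fold gave the mean difference from the reference (counts by list use the adjusted p alone unless the minimum is named), and a fit without linear time and with a term for the 0 min array gave the arrest comparison. P-values were adjusted by Benjamini-Hochberg over genes, or over the 20 lists, or over the 5 peak-time comparisons, with a threshold of 0.05. All tests of a difference are two-sided. Because all arrays follow 1 culture, p-values measure the scatter of these arrays around the curve and not the spread between cultures.

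The 20 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. That rule took YOX1 and YHP1, all ECB and marker genes, up to 4 genes per other list with the largest swing or change, and genome-wide the 10 genes with the largest swing among those periodic with r above 0.5 between cycles, and the 10 highest and 10 lowest past the threshold in each other comparison. List means were tested for a cycle with 100000 permutations of the time order, shares of periodic genes with Fisher's exact test, shifts with camera, and peak times by regrouping genes between lists, exactly or with 100000 permutations. Fitted folds are peak over trough of the curve. 1 of the 20 lists, which also enters 1 of the 5 peak-time comparisons, is not reported here, but it counts in every total and adjustment over lists. The ribosomal protein list was taken by a naming pattern that also matched RPP1, a gene of RNase P.

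The neighbouring arrays correlated with a median r of 0.807 across genes, and all pairs of arrays with 0.376 to 0.858 (median 0.612). The median residual scatter was 0.043 log10 units. On simulated data with this scatter, the periodic test on 6151 genes recovered 10.0% of genes with a 1.26-fold swing, 92.0% with 1.58-fold, 94.0% with 2.51-fold and 100% with 3.98-fold, with 12 false calls. The mean test on 6151 genes recovered 71.0% of 1.51-fold and 99.0% of 2.00-fold differences with 0 false calls. That simulation gave unchanged genes a true ratio of 1 to the reference, with no dye bias and no error of the reference pool. Its false calls therefore leave out calls that such offsets would make on the real arrays. The arrest test on 6109 genes recovered 48.5% of 1.58-fold, 80.6% of 2.00-fold and 96.9% of 3.16-fold differences with 11 false calls. The arrest simulation removed each gene's linear drift over time, which real genes keep and the arrest fit does not model. Its results can therefore look better than those on the real arrays. In 20 simulations of noise with a lag-1 correlation of 0.3 and no cycle, false periodic calls had a median of 0.5 and a maximum of 9.

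Alternatives were no centring, genes on all 13 or at least 7 arrays, no linear time, a second harmonic, other periods, leaving out arrays, array weights, a robust fit, other fold minimums and an estimated correlation in camera. Keeping the limited values and reading the values as log2 were added after seeing the data.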

Results

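Budding yeast of the W303 background, labelled as carrying mutations in YOX1 and YHP1, were held in G1 with the mating pheromone alpha factor and then released into rich medium. YOX1 and YHP1 encode related homeodomain repressors that act with Mcm1 at early cell cycle boxes (ECB), the promoter elements that restrict a group of genes to the M/G1 interval. RNA was sampled every 10 min from 0 to 120 min, which the labels describe as 2 cell cycles, and each of the 13 time points was hybridised to 1 two-colour array, so each group holds 1 sample and there are no replicates. The sample was labelled with Cy5 and RNA of an unsynchronised wild-type culture with Cy3, so a value above 0 means more RNA in the sample than in that reference. Values were present for 6065 to 6176 genes per array, and 6151 genes with at least 10 of 13 values were tested. The number of arrays limits the precision, and the error of each value below comes from the scatter of the 13 arrays around a fitted curve. A time course of wild-type cells was not analysed here, so no timing below is set against wild type. Folds take the deposited log ratios to be base 10, which was inferred from the values and is not given in the sources used here.

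The genes named in the strain label came first, because they check it, and 1 of them went against it. YHP1 (YDR451C) was below the reference on 13 of 13 arrays, with a mean log10 ratio of -0.27 ± 0.021 (SE, n = 13 arrays), which is 1.88-fold lower (adjusted p = 7.66e-08, limma). YOX1 (YML027W) was not evenly low. Its log10 ratio was -0.45 at 0 min, reached 0.07 at 30 min, fell to -0.53 at 60 min and was 0.12 at 80 min. This oscillation passed the test for a cycle (adjusted p = 0.00665), with a fitted peak at 26.0 ± 1.92 min (SE) and a peak 2.83-fold above the trough, and the call held under each alternative run. Over the whole course YOX1 was 1.30-fold lower than the reference (-0.12 ± 0.028, adjusted p = 0.00231) and below 0 on 10 of 13 arrays. YHP1 had a fitted peak-to-trough ratio of 1.59-fold and did not pass the test for a cycle (adjusted p = 0.0931), but did without the 80 min array (adjusted p = 0.0193) and with array weights (0.0447). As a list of 2, these genes had a mean profile that passed the permutation test for a cycle (adjusted p = 0.0160, and 0.0520 without the 30 min array), with 1 member periodic and 2 adjusted over the list alone. The mean profile correlated with r = 0.322 between the arrays of 10 to 60 min and those of 70 to 120 min. The kind of each mutation and the stretch of each gene on the array are not given in the sources used here, and a spot on a stretch still transcribed would check nothing. The samples are therefore called the cells labelled yox1 yhp1, and every direction below rests on that label.

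**Figure D1:**
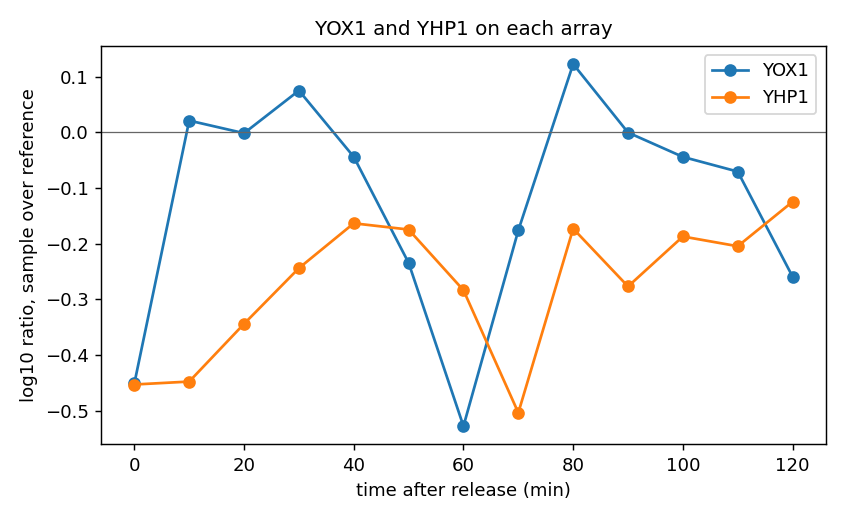
Log10 ratio of YOX1 and YHP1 (vertical axis, sample over reference, base inferred) against time after release in min (horizontal axis), 1 point per array. YHP1 lies below 0 at all 13 times, whereas YOX1 rises to 0.07 at 30 min, falls to -0.53 at 60 min and returns to 0.12 at 80 min.

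The first comparison asked which genes rose and fell with the cell cycle. The 10 genes of largest amplitude were taken among periodic genes with r above 0.5 between the cycles, and 6 of them were core histone genes. HTA1 (YDR225W) had the widest swing, 10.2-fold from trough to peak, with HTA2 at 7.91-fold, HHF1 7.33-fold, HHF2 7.22-fold, HTB1 7.20-fold and HTB2 6.54-fold, all with fitted peaks between 28.3 and 29.2 min after release (adjusted p from 4.19e-05 to 0.000103). The remaining genes among these 10 were MCD1, which encodes a cohesin subunit (7.50-fold, peak 17.7 ± 0.919 min, SE), RNR1, the large subunit of ribonucleotide reductase (7.06-fold, 17.5 ± 1.16 min), CHS2, the chitin synthase of the division septum (5.99-fold, 50.4 ± 1.84 min), and ACM1, an inhibitor of the anaphase-promoting complex (5.97-fold, 17.2 ± 1.36 min). EGT2 (7.69-fold, r = -0.223) and HO (6.27-fold, r = 0.442) were periodic but did not meet that limit. Without the linear time term EGT2 lost its call (adjusted p = 0.532, amplitude 0.26 instead of 0.44 log10 units), as did HO (0.245, amplitude 0.25 instead of 0.40). With a period 5 min shorter EGT2 (0.215), HO (0.0537) and CHS2 (0.0818) lost it, and with a second harmonic EGT2 (0.138) and CHS2 (0.0924). EGT2 also lost it with a period of 60 min (0.107), a robust fit (0.0789) and without the 30, 40, 50, 70, 80 or 100 min array (adjusted p from 0.0524 to 0.0947). In all, 975 of 6151 genes (15.9%) passed the limma F test for a cycle of 63 min, the period that fitted the mean of the G1/S list best. Of these, 797 also correlated with r above 0.5 between the 6 arrays of 10 to 60 min and the 6 of 70 to 120 min. The median peak-to-trough ratio of periodic genes was 1.54-fold, with quartiles of 1.39 and 1.90. Peaks were spread over the cycle, with 226 genes peaking from 10 to 20 min, 195 from 50 to 60 min and 77 from 0 to 10 min. The count depends on the curve fitted: it was 239 with a second harmonic, 622 with a period 5 min shorter and 1601 with array weights, and leaving out the 20, 30, 40 or 50 min array gave 587, 611, 560 and 501.

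Lists fixed beforehand peaked in succession. Among the 33 measured genes of the G1/S list, targets of the transcription factors SBF and MBF, all 33 were periodic (33 adjusted over the list alone), and the list mean peaked at 18.8 ± 1.14 min (SE) with a 2.93-fold swing (adjusted permutation p = 0.000733). The period was fitted on this list, so its own periodicity is not independent evidence. Its members included CLN2, a G1 cyclin (5.60-fold, 17.7 ± 1.07 min), and SVS1 (5.11-fold, 20.3 ± 0.634 min). All 9 histone genes were periodic, and their mean swung 6.31-fold with a peak at 28.9 ± 1.10 min (adjusted permutation p = 0.0003). The S/G2 list followed at 35.7 ± 0.890 min with a smaller swing of 1.53-fold and 7 of 10 members periodic (adjusted permutation p = 0.0003, 10 adjusted over the list alone), among them the forkhead factors FKH1 (2.75-fold) and FKH2 (2.00-fold) and the kinesin CIN8 (1.90-fold). With a second harmonic 4 of its members were called. The CLB2 cluster, genes of G2 and mitosis, peaked at 47.8 ± 2.16 min with a 2.71-fold swing and 14 of 17 members periodic (15 adjusted over the list alone), among them HOF1 (4.71-fold), the B-type cyclin CLB2 (4.38-fold) and the polo kinase CDC5 (4.08-fold). Its adjusted permutation p was 0.0258, and 0.0763 with a period of 60 min, 0.126 with a period 5 min shorter, 0.164 with a second harmonic, and 0.0636, 0.0883, 0.0722 and 0.0556 without the 40, 50, 80 and 90 min arrays. Its 14 periodic members were 4 with a second harmonic or a period 5 min shorter, 9 without the 40 min array and 7 without the 50 min array, where HOF1 and CDC5 had adjusted p of 0.0705 and 0.0532. HOF1, CLB2 and CDC5 lost their calls with a second harmonic (adjusted p = 0.126, 0.0752 and 0.0986) and with a period 5 min shorter (0.133, 0.0627 and 0.0899), and HOF1 with a period of 60 min (0.0598).

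Ranges of these list means were smaller in the second cycle. The G1/S mean spanned 0.60 log10 units at 10 to 60 min and 0.32 at 70 to 120 min, with r = 0.967 between the 6 matching times. The corresponding ranges were 0.86 and 0.54 for histones (r = 0.959), 0.22 and 0.16 for the S/G2 list (r = 0.959) and 0.64 and 0.37 for the CLB2 cluster (r = 0.875). These are values without a test.

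**Figure D2:**
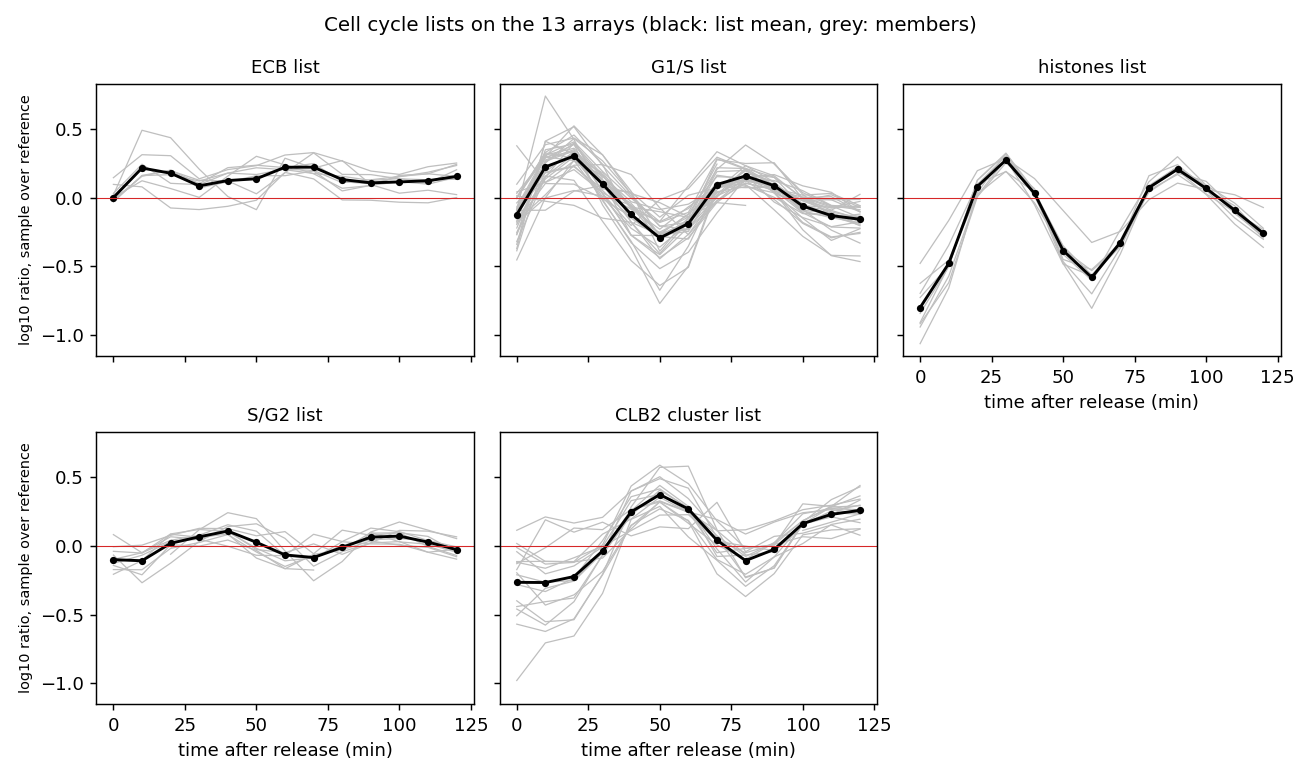
Log10 ratio (vertical axis, sample over reference, base inferred) against time after release in min (horizontal axis) for 5 lists. Black lines with points are list means, grey lines are single genes and the thin horizontal line marks 0; histones swing 6.31-fold and the ECB list 1.21-fold from fitted trough to peak.

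Outside the cell cycle lists, genes of growth and metabolism also passed the test for a cycle. In the ribosome biogenesis list 9 of 19 members were periodic (13 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00356), and the list mean peaked at 52.9 ± 2.03 min (SE) with a 1.35-fold swing (adjusted permutation p = 0.00950). Among them, RPA43, a subunit of RNA polymerase I, changed 1.65-fold and the nucleolar protein gene NOP58 1.58-fold. The count was 3 with a second harmonic, and 4 and 3 without the 20 and the 50 min array. The respiration list peaked at 15.0 ± 1.33 min with a 1.28-fold swing (adjusted permutation p = 0.00150) and 8 of 20 members periodic (10 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0205), such as SDH1 of succinate dehydrogenase (2.15-fold) and QCR2 of the cytochrome bc complex (1.80-fold). Without the linear time term the list's adjusted p was 0.166 and 5 members were called, and with a second harmonic or a shorter period 3 or 4 were. Leaving out the 20, 30, 40, 50 or 60 min array also left 5. The mean of 9 adenine genes peaked at 53.2 ± 1.58 min (adjusted permutation p = 0.00284, 1.24-fold) although only ADE1 (1.66-fold, 50.6 ± 1.29 min) was periodic by itself (3 adjusted over the list alone), and 2 were without the 0, 70 or 80 min array. In contrast, 3 of 137 genes in the ribosomal protein list were periodic (0 adjusted over the list alone), fewer than among all genes (Fisher's exact test, adjusted p = 1.56e-06). They included RPL5 (1.34-fold) and RPP1 (1.32-fold), and the latter encodes an RNase P subunit that the list's naming pattern took in. RPL5 lost its call without the 0, 20, 30, 40, 50 or 60 min array (adjusted p from 0.0552 to 0.0818), RPP1 without the 40, 50 or 100 min array (0.0529 to 0.101). Both lost it with a second harmonic (adjusted p = 0.138 and 0.192), RPL5 with a period 5 min shorter (0.0618), and RPP1 without the linear time term (0.0970) or with a period 5 min longer (0.0994). Between 0 and 5 members of that list were called with 1 array left out.

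For the other lists, the list mean did not pass the permutation test over the 13 arrays. Adjusted p was 0.906 for amino acid genes (0 of 21 periodic), 0.610 for alpha-specific genes (0 of 4), 0.561 for glycolysis (1 of 15), 0.484 for phosphate genes (2 of 11), 0.385 for the pheromone response (3 of 19), 0.282 for the stress response (5 of 19), 0.281 for ribosomal proteins, 0.116 for a-specific genes (1 of 7) and 0.0955 for methionine genes (3 of 18). Without the 0 min array the phosphate and methionine lists passed (adjusted p = 0.0154 and 0.0409, permutation test), and they then had 6 and 8 periodic members. The a-specific list passed without the 60 min array (adjusted p = 0.0262) and without the 0 and 10 min arrays (0.00558), and the methionine list without the 10 min array (0.0109, permutation test). The ribosomal protein list passed without the 120 min array (adjusted p = 0.0259). Between the cycles of 10 to 60 and 70 to 120 min, r was 0.063 for phosphate, 0.374 for methionine, 0.600 for a-specific and -0.580 for ribosomal protein genes. A pass of the phosphate, methionine or ribosomal protein list therefore does not show a profile that recurs. Adjusted over the list alone, periodic members numbered 8 for methionine genes, 8 for the stress response, 3 for the pheromone response, 2 for phosphate genes, 1 for a-specific genes and 0 for the amino acid, alpha-specific and glycolysis lists. With 1 array left out, periodic members ranged from 1 (without 50 min) to 6 in the stress list, from 1 (without 20, 30 or 40 min) to 3 in the pheromone list, from 1 (without 30 min) to 8 (without 0 min) in the methionine list, and from 0 to 2 in glycolysis. The phosphate list held 1 with a second harmonic, without the linear time term or with a shorter period. The a-specific list held 0 without the 20, 30, 40, 50, 70, 80 or 120 min array. The 7 genes often used as markers in W303 strains passed as a list (adjusted permutation p = 0.0216, swing 1.11-fold), with URA3 the periodic member (1.51-fold, 53.1 ± 1.51 min, adjusted p = 0.00231; 2 adjusted over the list alone). The mean of the marker list correlated with r = 0.120 between the 2 cycles, so a recurring profile was not shown. That list had an adjusted p of 0.503 without the linear time term, 0.120 with a second harmonic, 0.0551 with a period 5 min shorter, and 0.0501, 0.0906 and 0.0503 without the 20, 80 and 110 min arrays.

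The next comparison asked when genes under ECB control, the targets of the repressors named in the label, peaked in these cells. The ECB list held the G1 cyclin gene CLN3, the SBF subunit gene SWI4, the replication licensing gene CDC6 and the 6 genes MCM2 to MCM7 of the replicative helicase. CLN3 and SWI4 were periodic: CLN3 (YAL040C) swung 1.55-fold with a peak at 2.21 ± 2.27 min (SE, adjusted p = 0.0171), and SWI4 (YER111C) 2.34-fold with a peak at 14.8 ± 2.14 min (adjusted p = 0.0299). The count adjusted over the list alone was also 2 of 9. CLN3 lost its call with a period 5 min shorter (adjusted p = 0.0728) and without the 30 min array (0.0553). SWI4 lost it with a second harmonic (0.173), a period 5 min longer (0.0893) and without the 20, 30, 40 or 50 min array (0.0669, 0.0517, 0.0832 and 0.109), so neither call held under all settings. CDC6 had a fitted swing of 1.49-fold (adjusted p = 0.269), MCM2 of 1.41-fold (0.102), MCM5 of 1.35-fold (0.112), and MCM3, MCM4, MCM6 and MCM7 of 1.02-fold to 1.11-fold (0.786 to 0.995). The list mean swung 1.21-fold, with an upper 95% limit of 1.59-fold, and peaked at 8.66 ± 6.11 min (adjusted permutation p = 0.445). Its 2 cycles correlated with r = 0.792 over 6 matching times.

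This result rested on the arrest array. Without the 0 min array the ECB list passed the test (adjusted permutation p = 0.00309), swung 1.30-fold and peaked at 2.85 ± 1.71 min (SE), and 4 of its 9 members were periodic. Besides CLN3 (adjusted p = 0.0264) and SWI4 (0.0108), these were MCM2, with a 1.62-fold swing and a peak at 55.3 ± 1.68 min (adjusted p = 0.00486), and MCM5, with a 1.43-fold swing and a peak at 4.46 ± 1.98 min (adjusted p = 0.00990). Without the 0 and 10 min arrays the list's adjusted permutation p was 0.00558 with 5 members periodic. Leaving out any other array gave list values from 0.356 to 0.678. With array weights 4 members were periodic, 1 was with a second harmonic, with a period 5 min shorter or longer or without the 20, 40 or 50 min array, and 0 were without the 30 min array.

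Peak times of the ECB genes were set against those of other lists by regrouping members between lists, which is a test across genes and not across replicates. All 9 ECB members entered, since fewer than 3 were periodic. Of these, 7 had no cycle that passed, and the SE of the peak was 70.5 min for MCM6, 13.1 min for MCM3, 13.7 min for MCM4 and 16.2 min for MCM7, so the differences over all 13 arrays set no order by themselves. The circular mean lay at 4.30 min. It differed by -14.8 min from that of the 33 periodic G1/S genes (permutation p = 1e-05, the smallest these permutations can give) and by 19.4 min from that of the 14 periodic genes of the CLB2 cluster (exact permutation p = 1.22e-06, adjusted p = 6.12e-06). From the 9 histone genes it differed by -24.7 min (exact permutation p = 0.00288, adjusted p = 0.00480). From the 7 periodic S/G2 genes it differed by -30.3 min (exact permutation p = 0.132), close to the largest distance that a 63 min cycle allows. Without the 0 min array, where the 4 periodic ECB genes entered instead, the differences were -15.8 min from G1/S genes (adjusted permutation p = 0.000424), 16.6 min from the CLB2 cluster (0.000516), -26.2 min from histones (0.0175) and 31.3 min from S/G2 genes (0.0175). Without the 70 min array they were -24.6 min from G1/S genes and 10.0 min from the CLB2 cluster. The sign against histones turned with a period 5 min longer (33.7 min) and without the 70 min array (28.3 min), and did not pass without the 20 or 110 min array (adjusted permutation p = 0.0897 and 0.0662).

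Against the unsynchronised wild-type reference, genes of amino acid and methionine synthesis were higher and genes of ribosome biogenesis lower, averaged over the time course, by camera at a preset correlation. With an estimated correlation these list shifts did not pass (adjusted p = 0.350 for methionine and for amino acid genes and 0.20 for ribosome biogenesis, limma). The reference is 1 RNA pool labelled with 1 dye, so its own spread and any dye effect are part of each difference. Samples and reference also differ in labelled genotype, in arrest and release by alpha factor, and in culture. These cannot be told apart here, so no difference can be assigned to the mutations. Control spots for other organisms also lay above 0, as given at the end. The mean averages log ratios over time, whereas the pool averages RNA over cells of all phases. A gene with a wide swing, such as a histone gene, can therefore fall below 0 without a change in average level. How far was not tested, and the G1/S list, with a 2.93-fold swing, had a median of 0.022 log10 units. Of 6151 genes, 163 were at least 1.5-fold higher and 261 at least 1.5-fold lower with an adjusted p under 0.05. With a 2-fold minimum these counts were 17 and 48, and with none 2073 and 1969. The highest were PRY1, a secreted sterol-binding protein gene (6.22-fold, 0.79 ± 0.047 log10 units, SE), ARG1 (3.69-fold) and HIS4 (3.07-fold) of arginine and histidine synthesis, the chaperone gene HSP104 (2.43-fold), glucokinase GLK1 (2.38-fold), SAM3 (2.33-fold), CIT1 (2.31-fold), MMP1 (2.27-fold), SED1 (2.14-fold) and IDH1 (2.12-fold). Each of these 10 was above 0 on 13 of 13 arrays. The lowest were BSC1 (10.1-fold lower, SE 0.046 log10 units), PRM7 (8.52-fold), DUG1 (5.81-fold), DSE2 (5.78-fold), FRE4 (3.95-fold), SCW11 (3.32-fold), EGT2 (3.25-fold), OLE1 (2.99-fold), DSE1 (2.96-fold) and BAR1 (2.90-fold). BSC1, PRM7, DUG1, DSE2, FRE4 and OLE1 were below 0 on 13 of 13 arrays, SCW11, DSE1 and BAR1 on 12 and EGT2 on 10.

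Counts by list below rest on the adjusted p alone, by which 33.7% of all genes were higher and 32.0% lower, and those at the 1.5-fold minimum stand beside them. By list, 14 of 18 methionine genes were higher and 1 lower than the reference, 11 of them by at least 1.5-fold, with a list median of 0.20 log10 units (3 lower without the 10 min array). MET10 (2.11-fold), the methionine permease gene MUP1 (2.06-fold) and MET14 (1.97-fold) were among them. Of 21 amino acid genes, 17 were higher and 2 lower (9 higher by at least 1.5-fold), with a median of 1.33-fold, and 1 was lower without the 0, 10, 50, 60, 80, 90, 100 or 110 min array. Of 19 stress response genes, 17 were higher and 0 lower (median 1.32-fold), 4 of them by at least 1.5-fold (2 without the 10 min array), among them HXK1 (1.57-fold). Of 20 respiration genes 19 were higher and 0 lower (median 1.17-fold), but 1 by at least 1.5-fold, CYT1 (1.66-fold). All 19 ribosome biogenesis genes were lower, 11 of them by at least 1.5-fold, among them the helicase gene DBP3 (1.98-fold), NOG1 (1.96-fold) and NOP7 (1.87-fold). In the histone list 8 of 9 were lower (median 1.41-fold), 3 by at least 1.5-fold (1 with a period 5 min shorter or without the 0 and 10 min arrays, 5 with a period 5 min longer). Part of the histone difference can come from averaging log ratios of genes with a wide swing, and how much was not tested. Of 11 phosphate genes 6 were lower and 1 higher (2 without the 0 min array), with PHO89, a phosphate transporter gene, lowest (2.38-fold) and the 1 past the 1.5-fold minimum. In the ECB list 8 of 9 were higher and 0 lower, with a median of 1.41-fold, but 1 by at least 1.5-fold (3 without the 0 min array). This was MCM5 at 1.73-fold (0.24 ± 0.014 log10 units, SE, adjusted p = 9.24e-09), and CLN3 was at 1.02-fold (adjusted p = 0.549).

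With camera at a preset correlation of 0.01, 9 of 20 lists were shifted in this comparison, among them ribosome biogenesis (adjusted p = 2.93e-10), respiration (8.15e-06), stress response (4.79e-05), methionine (6.61e-05), amino acid (6.61e-05), ECB (0.00140), histone (0.00231) and phosphate genes (0.0400). With an estimated correlation 0 of 20 passed in limma, and the adjusted p was 0.20 for ribosome biogenesis and respiration, 0.350 for the stress response, methionine, amino acid and ECB lists, 0.501 for the histone list and 0.614 for phosphate genes. Adjusted over the list alone, 15 methionine, 19 amino acid, 17 stress, 19 respiration, 19 ribosome biogenesis, 8 histone, 7 phosphate and 8 ECB genes differed from the reference.

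The other lists showed no shift by camera. YOX1 and YHP1 were both lower, and the remaining lists had members on both sides of the reference. Their counts again rest on the adjusted p alone. In the G1/S list 11 genes were higher (7 without the 20, 110 or 120 min array) and 10 lower (21 adjusted over the list alone), in the CLB2 cluster 8 and 2 (10), in the S/G2 list 2 and 3 (5), in the ribosomal protein list 39 and 30 of 137 (66), in glycolysis 8 and 2 of 15 (12; 1 lower without the 0, 50, 70, 80, 90, 100 or 110 min array), and in the adenine list 6 and 1 of 9 (8). The pheromone list had 3 higher and 5 lower of 19 (8 adjusted over the list alone), and 12 lower without the 0 min array and 1 higher without the 90, 100, 110 or 120 min array. The a-specific list had 1 higher and 3 lower of 7 (4), and the alpha-specific list 1 and 1 of 4 (2), with 2 lower without the 0, 10 or 100 min array and 2 higher without the 120 min array. The marker genes TRP1 (1.87-fold), LYS2 (0.18 log10 units), HIS3 (1.34-fold), ADE2 (1.33-fold) and LEU2 (1.11-fold) were higher and CAN1 was lower (-0.081 log10 units), 6 adjusted over the list alone. LEU2 lost its call without the 40 or 90 min array (adjusted p = 0.0550 and 0.0608, limma) and without the 0 and 10 min arrays (0.0751). URA3 was at 1.04-fold below the reference (adjusted p = 0.148, and 0.0457 without the 0 and 10 min arrays). At the 1.5-fold minimum 0 genes of the S/G2, alpha-specific, adenine, glycolysis and ribosomal protein lists were called. The G1/S list then held 0 higher and 1 lower (0 without the 0 or 90 min array, 2 without the 10, 20 or 110 min array), and the a-specific list 0 and 2. The CLB2 cluster held 2 higher and 0 lower, and 1 and 1 without the 40, 50, 60 or 70 min array. The pheromone list held 2 higher (0 without the 0, 90, 100 or 110 min array, 1 without the 10, 80 or 120 min array) and 3 lower (6 without the 0 min array). The marker list held 2 higher, TRP1 and LYS2, and 1 without the 10, 20, 40, 70, 110 or 120 min array. A mutant allele carried by the strain can still give RNA, and the genotype at these loci is not given in the sources used here.

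The last comparison set the 0 min array, with cells held by alpha factor, against what the later cycles give for the same phase. Pheromone-induced genes stood far above their cycle level. The agglutinin anchor gene AGA1 was 27.1-fold higher, the cell fusion genes PRM1 and FUS1 19.5-fold and 12.8-fold, the pheromone protease gene BAR1 11.3-fold, AGA2 10.4-fold, the mating regulator KAR4 10.2-fold, SST2, which dampens pheromone signalling, 10.0-fold, PRM6 8.18-fold, FIG1 7.73-fold and PRM2 6.89-fold (adjusted p from 9.38e-08 to 0.00863, limma). AGA1 had an adjusted p of 0.0505 with a robust fit. In the pheromone list 16 of 19 genes were higher at arrest and 0 lower (18 adjusted over the list alone), with a median of 4.41-fold. The list mean was 0.63 log10 units above the reference at 0 min, 0.03 at 10 min and -0.15 at 20 min. In the a-specific list 4 of 7 were higher (6 adjusted over the list alone; median 4.69-fold), including the receptor gene STE2 (5.19-fold), whereas 0 of 4 alpha-specific genes, which a cells do not express, were called (0 adjusted over the list alone, median 1.06-fold).

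Of 17 genes of the CLB2 cluster, 6 were lower at arrest than their cycle level and 0 higher (17 adjusted over the list alone), and the list shift by camera had an adjusted p of 0.0538 with an estimated correlation. CLB1 was 8.32-fold lower, HST3 4.35-fold and HOF1 4.34-fold. The fit sets 0 min at the phase of 63 min, where this cluster was still high. The cluster mean was -0.26 log10 units at 0 min, 0.27 at 60 min and 0.26 at 120 min. At 10 and 20 min it was -0.27 and -0.22, so the arrest value matched the low point of the first cycle. The lower values of this cluster at arrest therefore cannot be told apart from the phase assumed for arrested cells. In that cluster 13 were lower without the 10 min array and 3 with array weights, where HOF1 lost its call (adjusted p = 0.0506). Also among the 10 lowest were YRO2 (6.05-fold), the hexose transporter gene HXT2 (5.80-fold), PRY1 (5.72-fold), SUR7 (5.12-fold), YGP1 (3.72-fold), CIS3 (3.69-fold) and MMR1 (3.41-fold). With a period 5 min shorter HXT2 (-0.52 instead of -0.76 log10 units, adjusted p = 0.147) and YRO2 (0.0744) lost their calls, and with a period 5 min longer SUR7 did (0.131). HXT2 (0.0514) and SUR7 (0.0797) also lost theirs with array weights, and YRO2 (0.0518) and SUR7 (0.0813) with a robust fit. SUR7 lost its call without the 30, 40, 50, 60, 70, 100 or 120 min array (adjusted p from 0.0548 to 0.0801). In the ECB list 5 of 9 genes were lower at arrest: CDC6 (2.58-fold, adjusted p = 0.00241), MCM4 (1.84-fold), MCM2 (1.69-fold), MCM6 (1.68-fold) and MCM5 (1.49-fold). This was 7 adjusted over the list alone, and the count was 3 with a second harmonic and 1 with array weights. With array weights MCM2 (adjusted p = 0.181), MCM4 (0.0514), MCM5 (0.258) and MCM6 (0.0763) lost their calls, and with a second harmonic MCM2 (0.106) and MCM5 (0.183). MCM2 also lost it with a period 5 min longer (0.0675), and MCM5 with a period of 60 min (0.0865) or 5 min shorter (0.185). MCM5 lost its call without the 40, 50, 60, 70, 90, 100 or 110 min array (adjusted p from 0.0526 to 0.0775). CLN3 was at 1.01-fold (adjusted p = 0.980) and SWI4 at 1.61-fold below its cycle level (adjusted p = 0.464). CLN1 was the 1 member of the G1/S list called, 2.60-fold lower (3 adjusted over the list alone). It lost its call with a period of 60 min (adjusted p = 0.132), a period 5 min shorter (0.360) and array weights (0.124). In the 2 shorter periods the list held 0 lower and 1 higher gene instead, PCL2 (0.0288 and 0.0196), which was also called without the 10 or 70 min array (0.0407 and 0.0182). PCL1 was called lower without the 80 min array (0.0300) and with a period 5 min longer (0.0337). The stress list held 1 call, YGP1. In the histone list 0 of 9 were called (7 lower adjusted over the list alone, median 2.17-fold), and 4 were lower without the 10 min array. The list of YOX1 and YHP1 and the S/G2, methionine, phosphate, adenine, amino acid, ribosomal protein, ribosome biogenesis, respiration, glycolysis and marker lists held 0 calls, and 0 adjusted over the list alone.

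In total 53 genes were higher and 51 lower at 0 min among 6109 tested, and 735 had an unadjusted p under 0.05. The term rests on 1 array, taken to vary like the other 12. Without the 10 min array the counts were 81 and 103, with a second harmonic 35 and 29, and with array weights 29 and 17. Of 20 lists, 10 were shifted by camera at the preset correlation and 3 with an estimated one: the pheromone response (adjusted p = 0.000460), a-specific genes (0.0158) and the ECB list (0.0158, lower). The other 7 lost the call, with an adjusted p of 0.0538 for the CLB2 cluster, 0.335 for histones, 0.371 for respiration, 0.459 for ribosome biogenesis, 0.487 for glycolysis, 0.624 for the stress response and 0.716 for the G1/S list with an estimated correlation.

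**Figure D3:**
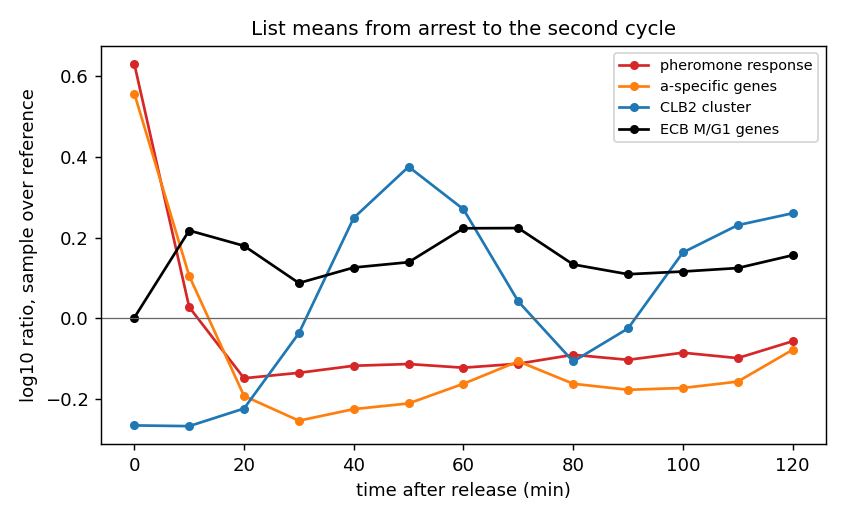
Mean log10 ratio of 4 lists (vertical axis, sample over reference, base inferred) against time after release in min (horizontal axis), 1 point per array. The pheromone list stands at 0.63 at 0 min and -0.15 at 20 min, and the ECB list at 0.00 at 0 min and 0.22 at 10 min.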

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

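Alternatives were set before the data were examined, except keeping values at the limit and reading them as log2. A rule for several probes per gene was not run, because each gene has 1 row. The cause of each shift below was not tested, except that other fold minimums and log2 change the threshold itself. Against 975 periodic genes, a second harmonic gave 239, a period 5 min shorter 622 and array weights 1601, and leaving out 1 array gave 501 (without 50 min) to 1038 (without 70 min), with 496 of the 501 shared with the 975. Genes higher at arrest (53) numbered 35 with a second harmonic, 29 with array weights and 42 to 81 with 1 other array left out, and genes lower (51) 29, 17 and 42 to 103. Periodic lists (9 of 20) were 14 without the 0 and 10 min arrays and 7 to 12 without 1 array. Lists shifted in the mean fell from 9 to 0 and at arrest from 10 to 3 with an estimated correlation. Genes higher than the reference (163) were 2073 with no fold minimum, 17 with 2-fold and 3 read as log2, and genes lower (261) 1969, 48 and 6. Leaving out 1 array gave 140 to 175 and 245 to 273. The ECB peak differed from histones by -24.7 min, by 33.7 min with a period 5 min longer, and without 1 array by -29.6 min (10 min array) to 28.3 min (70 min array). Against S/G2 genes (-30.3 min) it passed the test with genes on all 13 arrays (-31.5 min), a second harmonic (30.1 min) and without the 0 (31.3 min), 40 (-28.0 min) or 70 min array (22.7 min), and leaving out 1 array gave -29.7 min to 31.3 min. Differences near the largest that the period allows change sign by wrapping around the cycle. Differences from G1/S genes and the CLB2 cluster kept their sign and side of the threshold in all alternatives run, but those over all 13 arrays rest mostly on ECB genes without a called cycle, and without the 70 min array they went from -14.8 to -24.6 min and from 19.4 to 10.0 min. That from G1/S genes was -24.2 min with a period 5 min longer. Of calls of named genes in the mean and arrest comparisons, 0 changed sign. An amplitude cannot be negative, so a change of sign could not be seen for the calls of a cycle. Without the centring, each count over all genes stayed within 1.5 times, but periodic adenine genes were 2 instead of 1, and amino acid and glycolysis genes lower than the reference were 1 each instead of 2. In lists, periodic stress genes (5) were 0 with a second harmonic, 1 with a period 5 min shorter and 9 with array weights, methionine genes (3) 1 with a second harmonic, 9 with array weights and 11 without the 0 and 10 min arrays, pheromone genes (3) 0 with a second harmonic, ribosomal protein genes (3) 0 with a second harmonic and 6 with array weights, and glycolysis genes (1) 5 with array weights. Without the 0 and 10 min arrays, CLB2 cluster genes higher than the reference (8) were 13 and pheromone genes lower (5) were 13. Signal over background is not known here, so its effect on weak spots cannot be given.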

Other observations

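The tests of YOX1 timing, of YHP1, of the ECB list and of the time order and single arrays were chosen after the result was seen. The tests on neighbouring genes were written before their counts were seen, but after BSC1 and PRM7 had been noticed side by side, and the count with 6 genes left out was added after the result was seen.

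Differences from the reference included genes that lie side by side. BSC1 (10.1-fold lower) and PRM7 (8.52-fold lower) are neighbours, as are the methionine-related transporter and transferase genes MMP1 (2.27-fold higher) and MHT1 (1.93-fold higher), the histone genes HTA1 (1.72-fold lower) and HTB1 (1.58-fold lower), the hexose transporter genes HXT6 (1.68-fold higher) and HXT7 (1.53-fold higher), and the subtelomeric helicase genes YRF1-4 (1.79-fold higher) and YRF1-5 (1.68-fold higher). HXT6 and HXT7 are near-identical copies, as are the YRF1 genes, and their spots may read each other's RNA. Other neighbours were lower together, such as UTP9 and RIX1 (1.97-fold and 1.83-fold), DBP8 and NMD3 (1.85-fold and 1.87-fold), PWP1 and NOP56 (1.84-fold and 1.67-fold) and BMT2 and MAK5 (1.67-fold and 1.92-fold). All pairs named here were picked after their values were seen. Of 401 called genes placed on chromosomes, 75 stood next to another called gene, in 38 neighbouring pairs, 30 of them with the same sign. Among 10000 random sets of as many genes, the median was 28 pairs and the central 95% of sets spanned 19 to 38 (one-sided permutation p = 0.0354). With BSC1, PRM7 and the HXT6, HXT7, YRF1-4 and YRF1-5 copies left out, 35 pairs remained (median 27, one-sided permutation p = 0.0810), so chance placing stays open. Next to another called gene were 18.7% of the called genes, which argues against a few differing chromosome segments as the source of most calls. All 19 genes of the ribosome biogenesis list were lower than the reference. How far neighbouring genes of that kind raise the number of pairs was not tested. Strain differences at single loci stay open and were not tested, and no biological explanation was tested.

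YOX1 rose and fell on arrays labelled yox1 yhp1. The peak times cannot decide whether RNA of the related gene YHP1 bound the YOX1 spot. The fitted peaks differed by 14.3 min with a combined SE of 3.50 min. However, the cycle of YHP1 did not pass the test (adjusted p = 0.0931, limma). The levels, compared after the result was seen, argue against YHP1 RNA as the only source, as far as the YHP1 spot reads that RNA. YHP1 stayed below the reference on every array, whereas YOX1 rose above it on some. The fitted amplitude was 0.23 ± 0.039 log10 units (SE) for YOX1 and 0.10 ± 0.032 for YHP1. RNA still made at the YOX1 locus at the G1 to S boundary is a candidate that the timing cannot decide. The YOX1 peak at 26.0 min lay within the 11.7 to 31.6 min of the 33 G1/S genes, 2 of which peaked later. That range is wide and also holds the histone list peak (28.9 ± 1.10 min, SE), while the G1/S list mean peaked at 18.8 ± 1.14 min. Cells with both genes intact cannot be told apart from RNA still made at the YOX1 locus, since the mean of YHP1 lay at the 1.14 percentile of all tested genes (70 genes as low or lower) and no wild-type course was analysed here. The kind of each mutation is not given in the sources used here.

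Over all 13 arrays the ECB list showed no cycle that passed the test (adjusted p = 0.445). A lack of synchrony is argued against, since 9 of 9 histone genes, which did not set the period, were periodic. Their mean swung 6.31-fold, so they cannot show whether synchrony was too weak for a small swing. The S/G2 list, with a 1.53-fold swing, passed as well, but ranges of list means were smaller in the second cycle. Low values on the arrest array are a candidate explanation: without the 0 min array the adjusted permutation p was 0.00309, and without any other array it stayed between 0.356 and 0.678. Whether the small swing of 1.30-fold then seen differs from wild type was not tested, since no wild-type course was analysed here, and no biological explanation was tested.

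Among 100 random orders of the time points, with the period refitted, the highest count of periodic genes was 126, so that 1 of 101 orders, the real one, gave as many as 975, and chance order can be excluded. Singling out each of the 13 arrays in turn, 1 array, that of 0 min, gave 104 calls or more, and the highest of the others was 9. With 13 arrays the share cannot fall under 0.05.

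Control spots for RNA of other organisms had ratios with medians of 0.10 (E. coli), 0.14 (Phi174), 0.12 (Lambda) and 0.08 (human) log10 units, and the yeast control of -0.07. Blank spots had a median of 0.02, and the control spots named n1, n2, p1 and p2 had medians of 0.028, 0.010, 0.008 and 0.010. Medians of the stress, amino acid, ECB and respiration lists in the mean against the reference were 0.12, 0.12, 0.15 and 0.07. Their size is near that of the other-organism spots, so an offset towards Cy5 cannot be told apart from higher RNA in these lists. Such an offset was not seen on all spots, since the medians of the alpha-specific and ribosomal protein lists were -0.003 and 0.006.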
